A study of Mus musculus with 46 samples.

How the data were processed

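RNA-seq read counts per gene were analysed for 46 libraries of mouse microglia, the resident macrophages of the brain. Per the labels, the mice were wild type (WT, 22 libraries) or 5xFAD (labelled AD, 24 libraries), a transgenic mouse model of Alzheimer's disease. They were fed 1 of 3 diets: a diet without fiber (zero fiber), a control diet, or a diet with HAMSAB, a resistant maize starch carrying acetyl and butyryl groups, which gut bacteria release as short-chain fatty acids. Diet, genotype and sex define 12 groups, of 4 libraries each except zero_fiber_WT_M with 2. Libraries are named here by diet, genotype, sex (F or M) and a replicate number given in accession order, which pairs no libraries. The labels do not give the age, the time on the diet or how the microglia were isolated, and do not say that each library came from a separate mouse, so the p-values measure the spread between these libraries.

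Per the labels' protocols, RNA was extracted from the microglia on a QIAcube with an RNeasy Micro kit and made into libraries by standard Illumina protocols. The authors deposited 1 table of raw read counts for 54134 gene symbols, with 1 column per library and no normalization. STAR 2.5.2b, featureCounts 1.5.2 and the mouse build GRCm38 (mm10) are named per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads of near-identical genes, such as members of the H2 family, the alpha-globin genes or ribosomal protein genes with pseudogenes, may therefore have been split or dropped, and a gene cannot be told from one that overlaps it on the other strand. Gene coordinates were taken from the GENCODE mouse annotation (release M21, GRCm38) by symbol, which placed 12009 of the 12121 tested symbols. The human transgenes were not analysed here.

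Total counts ran from 52114 to 6950429 per library, with a median of 2344837.5. The lowest total belonged to zero_fiber_AD_M replicate 2. No pair of libraries held identical counts, and the lowest chi-square per degree of freedom between replicates was 1.62, for a pair that included the library of lowest depth. Of the 54134 genes, 22686 had 0 counts in every library. The edgeR function filterByExpr left 12121 genes for testing.

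Every comparison came from 1 fit over all 46 libraries, with a mean for each of the 12 groups and a shared estimate of the spread (R 4.3.3, edgeR 4.0.16, TMM factors between 0.919 and 1.25, quasi-likelihood F test). Comparisons of diets or genotypes averaged the 2 sexes with equal weight, and comparisons of the sexes averaged the 3 diets. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 12121 genes were called. Fold changes are on the log2 scale with the standard error (SE) of the fit. Expression levels are CPM (counts scaled by TMM-adjusted library size), given as mean ± SD over libraries. There were 22 tests across all genes, 20 of them with a direction.

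The design, the tests, 27 gene lists and the rule for named genes were set before the data were examined. Lists with at least 5 tested members (22 of the 27) were tested with limma's camera (limma 3.58.1) on voom values at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The same lists were tested with an estimated correlation and with fry. The estimated-correlation p depends somewhat on the order in which the groups enter the fit, so values near 0.05 are unstable. The named genes of a comparison were the 10 largest increases and the 10 largest decreases among called genes with a mean log2 CPM of at least 1, leaving out unnamed and predicted genes, plus up to 4 called members of each list by p. Where fewer than 5 genes were called, the 5 of smallest p were taken. In the sex comparisons Xist and Y-linked genes came first, and 11 anchor genes of microglial and perivascular macrophage states could be named throughout. A called gene named outside this rule is marked as chosen after its values were seen.

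The alternatives set beforehand were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 test, limma voom with quality weights, a term for the series of the number in the library's title, a fit with only the libraries compared, and leaving out each library in turn. Title numbers fall below 2900 in 23 libraries and at 2900 or above in 22, and 1 library is numbered 000. The labels do not say that these are batches, and the title series was treated as a possible one. Chosen after the data were seen were a fit without the 2 doubted libraries, zero_fiber_AD_F replicate 1 (sex genes) and zero_fiber_AD_M replicate 2 (depth), and a fit with each library's trend on transcript length removed.

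The tests were tried on simulated counts drawn at the real means and library sizes, with a set of genes changed by known folds. In the simulated AD against WT comparison on the control diet (12091 genes), edgeR called 46.3% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 7 of 11878 unchanged genes. In the simulated HAMSAB against control comparison of AD males (12093 genes) it called 25.4%, 71.6% and 89.4% at these folds, and 11 of 11880 unchanged genes. Camera with the preset correlation called 0 of 21 unchanged lists in the first simulation and 1 of 21 in the second. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes vary together.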

Results

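Microglial transcriptomes were compared between AD and WT mice of both sexes on a zero-fiber, a control or a HAMSAB diet. There were 8 libraries for each diet and genotype except zero-fiber WT, which had 6. Total counts lay between 1174514 and 6950429 in 44 of the 46 libraries, and were 783849 and 52114 in zero_fiber_AD_M replicates 1 and 2. P2ry12, a purinergic receptor of homeostatic microglia (chromosome 3, 59216272 to 59262871, GRCm38), stood at 5527 ± 833 CPM in control WT and 5491 ± 1202 CPM in control AD mice (SD, n = 8 each). Tmem119, a microglial surface protein, stood at 3293 ± 278 and 3168 ± 343 CPM. The first principal component held 39.1% of the variance and set zero_fiber_AD_M replicate 2 apart (score 252.2, against -12.4 to 1.02 in the others).

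The sex labels were checked first, with Xist, the X-inactivation RNA (chromosome X, 103460366 to 103483254), and the Y-linked genes Ddx3y (chromosome Y, 1260771 to 1286629) and Eif2s3y. The library labelled zero_fiber_AD_F replicate 1 had 0.212 CPM of Xist (1 read), 141 CPM of Ddx3y and 64.4 CPM of Eif2s3y, a male pattern. The other zero-fiber AD females had 838 to 931 CPM of Xist. In zero_fiber_AD_F replicate 2 Xist was 838 CPM and Ddx3y was 17.8 CPM, and in HAMSAB_WT_F replicate 4 Ddx3y was 6.63 CPM, against 1.08 CPM or less in the other libraries of those 2 groups apart from the library labelled zero_fiber_AD_F replicate 1. Differences to which the library labelled zero_fiber_AD_F replicate 1 contributes Y-linked reads are marked as such below.

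HAMSAB was compared with the zero-fiber diet in AD mice to ask how the presence and kind of fiber in the diet relate to microglial expression in the disease model. MHC class I genes and interferon-inducible genes were higher on HAMSAB. H2-K1, a classical class I heavy chain (chromosome 17, 33996017 to 34000347), rose from 231 ± 50.8 to 531 ± 147 CPM (SD, n = 8 each; log2 fold change 1.14 ± 0.15, SE; adjusted p = 1.4e-05). H2-D1, the other classical heavy chain (chromosome 17, 35262730 to 35267499), rose from 369 ± 107 to 804 ± 166 CPM, and B2m, the class I light chain (chromosome 2, 122147686 to 122153083), from 2785 ± 567 to 4228 ± 376 CPM. The nonclassical class I genes H2-Q7 and H2-M3 rose by log2 2.24 ± 0.43 and 1.03 ± 0.17 (SE), and Nlrc5, a transactivator of class I genes, by 2.08 ± 0.48.

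All 10 tested members of the MHC class I list were higher on HAMSAB. H2-K1, H2-D1, B2m and Nlrc5 (4) were called and 6 were not. When adjusted over the list alone, 5 passed. Its median log2 fold change was 0.29 and camera gave adjusted p = 8.1e-12, or 0.00101 with an estimated correlation. All 28 members of the interferon response list were higher, with a median of 0.69 (camera adjusted p = 6.3e-20, and adjusted p = 0.0548 with an estimated correlation). Of these, 2 were called, Ifi27l2a (1.55 ± 0.33, SE) and Slfn2 (0.87 ± 0.19), both interferon-induced, and 18 passed when adjusted over the list alone. The mean log2 CPM of the interferon list was higher on HAMSAB by 0.95 in all libraries, by 1.18 among title numbers below 2900 (5 and 4 libraries) and by 0.86 among those of 2900 and above (2 and 4), with HAMSAB_AD_F replicate 4 in neither series. Without zero_fiber_AD_M replicate 2 it was 0.75 in all libraries and 0.73 below 2900, and without both doubted libraries 0.82 and 0.84, comparisons chosen after the data were seen. For the MHC class I list the differences were 0.61, 0.77 and 0.55. Both list calls held without any single one of the 16 libraries.

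**Figure D1:**
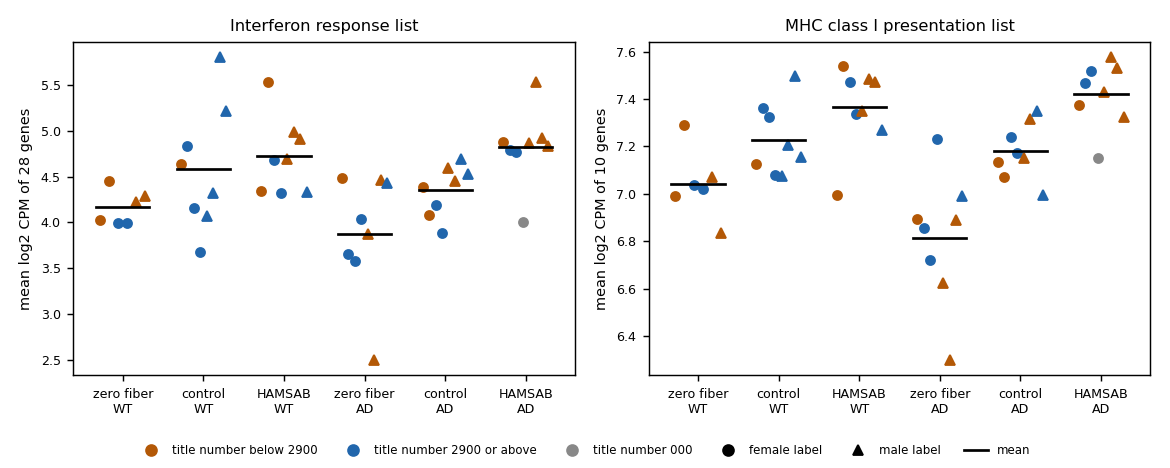
Mean log2 CPM of the 28 interferon response genes (left) and the 10 MHC class I genes (right) in each library, by diet and genotype. Each point is 1 library, its color gives the series of its title number, its shape the sex label, and the line is the group mean; 7 of the 8 HAMSAB AD libraries lay above every zero-fiber AD library in both panels, HAMSAB_AD_F replicate 4 did not, and the lowest point in both panels is a zero-fiber AD male.

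Among disease-associated microglia genes, 27 of 31 were higher on HAMSAB in AD mice and 4 lower, with 1 called and 11 passing when adjusted over the list alone (median 0.24, camera adjusted p = 1.7e-09, 0.0127 with an estimated correlation). The called gene was Axl, a receptor tyrosine kinase of apoptotic cell uptake (chromosome 7, 25757273 to 25788705), at 17.8 ± 4.92 against 40.9 ± 23.6 CPM (log2 1.08 ± 0.23, SE). Itgax, the CD11c integrin, had a log2 fold change of 1.0 ± 0.31 and Clec7a, a beta-glucan receptor, 0.97 ± 0.32, neither called. Apoe (0.11 ± 0.20) and Trem2 (0.22 ± 0.13) were not called either. The lysosome and phagocytosis list rose (16 of 19 higher, 0 called, 9 when adjusted over the list alone; median 0.17, camera adjusted p = 5.9e-07, 0.0127 with an estimated correlation). Rises in glycolysis (median 0.19), complement (0.13), ribosomal protein (0.14), nuclear respiratory chain (0.11) and proliferation genes (0.16) were called by camera. With an estimated correlation their adjusted p were 0.0919, 0.0919, 0.26, 0.357 and 0.156. The ribosomal and respiratory chain calls ended when the trend on transcript length was removed (adjusted p = 0.0878 for both, at medians of 0.06 and 0.04), and that trend differed between the diets (slope -0.0508 on HAMSAB and 0.0286 on zero fiber; exact permutation p = 0.0135, adjusted over 54 tests 0.183). Without the 2 doubted libraries the complement and proliferation calls ended (adjusted p = 0.0783 for both). The proliferation call also ended with the series term (0.056) and held in 9 of the 16 fits without 1 library (highest adjusted p 0.172, without zero_fiber_AD_M replicate 3).

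Erythroid and choroid plexus genes were lower on HAMSAB than on zero fiber (4 of 5, 0 called, 4 lower and 1 higher when adjusted over the list alone; median -2.35, camera adjusted p = 4.7e-06, 0.0236 with an estimated correlation). Hemoglobin transcripts, which come from red blood cells, made up 161 ± 129 CPM on zero fiber and 34.1 ± 52.1 CPM on HAMSAB (exact permutation p = 0.00513, two-sided, adjusted over 54 tests 0.0923). Neuron genes had a median of -0.33 (0 of 6 higher, 0 called; camera adjusted p = 0.0437, 0.26 with an estimated correlation). That call ended without the 2 doubted libraries (0.17) and with the length trend removed (0.0618, at a median of -0.34), and held in 8 of 16 fits without 1 library (highest 0.281, without zero_fiber_AD_M replicate 3). Perivascular macrophage genes had a median of -0.76 (0 of 9 higher, 0 called, 1 lower when adjusted over the list alone; camera adjusted p = 9.1e-04, 0.183 with an estimated correlation). The perivascular difference was 0.07 among title numbers below 2900 (-0.10 without zero_fiber_AD_M replicate 2) and -0.997 among those of 2900 and above, so it did not hold in the lower series.

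In this comparison edgeR called 20 genes higher and 9 lower. Other increases were Ms4a4c (log2 1.70 ± 0.30, SE), Slamf8, a SLAM family receptor of macrophages (1.52 ± 0.28), and Sp100, a nuclear body protein (1.29 ± 0.26). The largest decreases were the Y-linked genes Kdm5d, Ddx3y, Eif2s3y and Uty (-3.86 to -2.75). Most zero-fiber female reads of these genes came from zero_fiber_AD_F replicate 1. Without it Eif2s3y and Uty were not called (adjusted p = 0.157 and 0.23) and Ddx3y and Kdm5d were (0.025 and 0.0438). All 4 stayed lower in the 16 fits without 1 library, at smallest by -2.80 to -1.54. None left out both zero_fiber_AD_F replicates 1 and 2, though replicate 2 also held Y-linked reads, so no diet effect is shown. Next were Epb41l4a (-1.45 ± 0.34), Tshz1, a zinc finger homeobox gene (-0.72 ± 0.16), Tnrc18 (-0.64 ± 0.13) and Zfhx3 (-0.60 ± 0.14). H2-K1, H2-D1, B2m, H2-M3, H2-Q7, Ms4a4c and Slamf8 were called in all 16 fits that left out 1 library, while Axl was called in 13, Ifi27l2a in 10, Slfn2 in 9, Nlrc5 and Tshz1 in 5, Epb41l4a in 4 and Zfhx3 in 3. Without the 2 doubted libraries 27 genes were called, 18 of them shared with the 29. The count was 16 to 19 without HAMSAB_AD_F replicates 1 or 3, HAMSAB_AD_M replicates 2, 3 or 4, zero_fiber_AD_F replicates 2 or 3, or zero_fiber_AD_M replicates 1 or 4. It was 48 without HAMSAB_AD_M replicate 1 and 72 without zero_fiber_AD_M replicate 3. DESeq2 called 52 genes and edgeR with no low-count filter 204.

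HAMSAB was compared with the control diet in AD mice to ask whether the modified starch adds to a diet that already holds fiber. Of the 9 genes called, 8 were higher on HAMSAB and 1 lower. H2-T23, a nonclassical class I gene (chromosome 17, 36029773 to 36032855), rose from 58.0 ± 14.8 to 103 ± 20.7 CPM (SD, n = 8 each; log2 0.84 ± 0.14, SE; adjusted p = 0.0036), and H2-K1 from 330 ± 37.8 to 531 ± 147 CPM. Slamf8 (chromosome 1, 172581758 to 172590568) rose from 13.1 ± 2.28 to 33.3 ± 14.8 CPM, and H2-Ob, a chain of the H2-O modulator of class II loading (chromosome 17, 34238903 to 34254414), from 31.1 ± 20.6 to 99.0 ± 42.8 CPM. Ramp1, a subunit of the CGRP receptor (log2 0.61 ± 0.13), Abcc5, an ABC transporter (0.53 ± 0.11), and Cyp2r1, the vitamin D 25-hydroxylase (3.63 ± 0.78), also rose. Ifi202b, an interferon-inducible gene of chromosome 1, was called too and is named here after its value was seen. Olfml2b, an olfactomedin-like gene of chromosome 1, was the 1 gene that fell (-0.84 ± 0.17). H2-T23, H2-K1 and H2-Ob lay within 5 Mb of each other on chromosome 17, as did Slamf8, Ifi202b and Olfml2b on chromosome 1.

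The interferon response list was higher on HAMSAB than on control (27 of 28 members, 0 called, 7 when adjusted over the list alone; median 0.47, camera adjusted p = 2.6e-08, 0.395 with an estimated correlation), by 0.63 within the lower and 0.46 within the higher title series. MHC class I genes (7 of 10 higher, 1 called, 4 over the list alone; median 0.28) and disease-associated genes (23 of 31 higher, 0 called, 1 over the list alone; median 0.13) were called by camera at adjusted p = 0.00891 and 0.00669, each 0.395 with an estimated correlation. All 9 perivascular macrophage genes were lower on HAMSAB and all 9 passed when adjusted over the list alone, with 0 called over all genes (median -1.28, camera adjusted p = 2.0e-07, 0.139 with an estimated correlation). Mrc1, the mannose receptor, had a log2 fold change of -1.25 ± 0.34 and Cd163, the hemoglobin scavenger receptor, -1.67 ± 0.50, neither called over all genes. The perivascular difference was -1.48 in the lower title series (5 and 4 libraries) and -0.29 in the higher (2 and 4). Respiratory chain, ribosomal protein and neuron genes were called higher (medians 0.17, 0.15 and 0.60) and immediate early genes lower (-0.13), with adjusted p of 0.434, 0.434, 0.395 and 0.395 with an estimated correlation. The respiratory chain and ribosomal calls ended with the length trend removed (adjusted p = 0.32 and 0.355, at medians of 0.05 and 0.07). Among the 16 fits without 1 library the respiratory chain, ribosomal, neuron and immediate early calls held in 15, 14, 9 and 8, with the highest adjusted p (0.0568, 0.106, 0.107 and 0.165) without control_AD_F replicate 2, HAMSAB_AD_M replicate 1, HAMSAB_AD_M replicate 2 and control_AD_M replicate 3.

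The count of 9 genes called between HAMSAB and control in AD mice was 1 to 4 without control_AD_F replicates 1 or 2, control_AD_M replicates 1, 2 or 3, HAMSAB_AD_F replicate 1 or HAMSAB_AD_M replicate 3. It was 15 without HAMSAB_AD_F replicate 4, 44 without control_AD_M replicate 4, and 91 to 104 without HAMSAB_AD_M replicate 2, HAMSAB_AD_F replicate 2 or control_AD_F replicate 3. DESeq2 called 80 genes (8 of the 9 among them), voom with weights 72, only the libraries compared 71, a term for the title series 25, the fit without the 2 doubted libraries 19 and no low-count filter 357. H2-T23 was called in all 16 fits without 1 library and Slamf8 in 14, and the other named genes in 6 to 9.

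Zero fiber was then compared with the control diet in AD mice. Of the 7 genes called, all higher on zero fiber, 4 were the Y-linked Ddx3y (log2 3.54 ± 0.62, SE), Eif2s3y (3.30 ± 0.61), Kdm5d and Uty, to which the library labelled zero_fiber_AD_F replicate 1 contributed most of the female reads. Without the 2 doubted libraries these were not called (adjusted p = 0.0723, 0.105, 0.168 and 0.359) at log2 fold changes of 2.19, 1.94, 1.53 and 1.10, and zero_fiber_AD_F replicate 2 also held Y-linked reads (Ddx3y 17.8 and Eif2s3y 7.96 CPM). The others were Hba-a2, an alpha-globin gene (3.63 ± 0.75), Hectd4, a ubiquitin ligase domain gene (0.62 ± 0.12), and Gm44187, a predicted gene named after its value was seen. Hemoglobin transcripts stood at 161 ± 129 CPM on zero fiber and 30.3 ± 43.9 CPM on control (exact permutation p = 0.00373, two-sided, adjusted over 54 tests 0.0923). The erythroid and choroid plexus list rose (4 of 5, 1 called, 4 over the list alone; median 2.90, camera adjusted p = 2.1e-04, 0.0904 with an estimated correlation). All 6 neuron genes were higher (0 called, 3 over the list alone; median 0.87, camera adjusted p = 4.1e-05, 0.0904 with an estimated correlation). MHC class I genes were lower (9 of 10, 0 called, 5 over the list alone; median -0.30, camera adjusted p = 2.1e-04, 0.0904 with an estimated correlation), by -0.49 in the lower and -0.24 in the higher title series.

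Interferon response (22 of 28 lower, median -0.24), lysosome (16 of 19, -0.10), complement (9 of 10, -0.14), perivascular (8 of 9, -0.43) and disease-associated genes (22 of 31, -0.11) were also called lower by camera in zero-fiber against control AD mice. Their adjusted p with an estimated correlation were 0.609, 0.288, 0.219, 0.381 and 0.381, and none of their members was called. Without the 2 doubted libraries the disease-associated, perivascular, complement and lysosome calls ended (adjusted p = 0.124, 0.0636, 0.124 and 0.124). The perivascular difference was -1.55 in the lower title series and 0.71 in the higher. Among the 16 fits without 1 library the perivascular, disease-associated, interferon and complement calls held in 11, 13, 15 and 15, with the highest adjusted p (0.64, 0.163, 0.0558 and 0.0554) without zero_fiber_AD_M replicates 3 and 1, zero_fiber_AD_F replicate 3 and zero_fiber_AD_M replicate 2. Without the doubted libraries edgeR called 3 genes, none shared with the 7. The count was 0 without zero_fiber_AD_F replicate 1, control_AD_F replicate 2 or control_AD_F replicate 3, 2 to 4 without control_AD_M replicates 1, 2 or 3, and 12 without zero_fiber_AD_F replicate 4. Hba-a2 was called in 7 and Hectd4 in 10 of the 16 fits without 1 library. Voom with weights called 0, DESeq2 16, only the libraries compared 1 and no low-count filter 269.

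The same diet comparisons were made in WT mice. HAMSAB against zero fiber gave the most called genes of the diet comparisons, 226 higher and 39 lower. Itgax (chromosome 7, 128129547 to 128150657) rose from 1.94 ± 1.58 CPM (n = 6) to 9.32 ± 3.55 CPM (n = 8; log2 2.60 ± 0.42, SE; adjusted p = 5.5e-04). Axl rose from 17.7 ± 8.76 to 40.8 ± 18.9 CPM, Ccl4, a chemokine, from 40.1 ± 11.7 to 98.7 ± 30.1 CPM, and Csf1, the ligand of the Csf1 receptor, from 19.4 ± 3.11 to 29.6 ± 3.91 CPM. With these 4 called, 27 of 31 disease-associated genes were higher and 9 passed over the list alone (median 0.26, camera adjusted p = 7.1e-07, 0.0881 with an estimated correlation). Apoe (0.14 ± 0.22), Trem2 (-0.08 ± 0.14) and Cst7 (0.26 ± 0.24) were not called.

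In WT mice 27 of 28 interferon genes were higher on HAMSAB than on zero fiber, 2 of them called, Slfn2 (log2 0.87 ± 0.21, SE) and Rtp4 (0.96 ± 0.27), with 11 over the list alone (median 0.71, camera adjusted p = 4.4e-09, 0.475 with an estimated correlation). The difference was 0.64 in the lower and 0.45 in the higher title series. For MHC class I, 9 of 10 were higher, 1 called (Nlrc5, 1.49 ± 0.41) and 4 over the list alone (median 0.27, camera adjusted p = 5.9e-04, 0.139 with an estimated correlation). All 5 erythroid and choroid plexus genes were lower, 1 called (Hba-a1, an alpha-globin gene, -2.30 ± 0.55) and 4 over the list alone (median -2.03, camera adjusted p = 1.7e-06, 0.0597 with an estimated correlation). Hemoglobin transcripts stood at 286 ± 298 CPM on zero fiber and 61.0 ± 58.0 CPM on HAMSAB (exact permutation p = 0.0256, adjusted over 54 tests 0.231).

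Other large increases on HAMSAB in WT mice were Spock1, a proteoglycan (log2 2.89 ± 0.50, SE), Plin3, a lipid droplet protein (2.39 ± 0.47), Kif7, a kinesin-like protein of cilia (2.34 ± 0.57), Pced1b (1.99 ± 0.36), the RNA-binding gene Rbm45 (1.81 ± 0.38) and the class I gene H2-Q7 (1.74 ± 0.48). Also higher were Cux2, a homeobox gene (1.69 ± 0.30), Rsl24d1, a ribosome assembly factor (1.63 ± 0.35), and Ccdc85c (1.61 ± 0.36). Genes that fell included Tex11 (-4.29 ± 1.03), Slc15a2, a peptide transporter (-2.51 ± 0.62), Pde4d, a cAMP phosphodiesterase (-1.14 ± 0.28), and the chemokine Ccl24 (-1.14 ± 0.24), from 41.1 ± 14.3 to 18.7 ± 5.44 CPM. Olfr111, Syt6, Cdk5rap1, Zfp458 and Det1 fell by between 1.62 and 1.23 on the log2 scale. Tex11 averaged 0.351 CPM on HAMSAB and 2.94 ± 3.48 CPM on zero fiber, close to the limit of detection.

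Most of the 265 calls were lost without either zero-fiber WT male. These males also held the most hemoglobin transcripts of the zero-fiber WT libraries (659.7 and 680.5 CPM, against 65.3 to 129.5 CPM in the females). Whether this bears on the calls was not tested. The count was 1 without zero_fiber_WT_M replicate 2 and 12 without zero_fiber_WT_M replicate 1, where the remaining male is assumed to vary like the other groups. It was 131 to 171 without HAMSAB_WT_F replicates 1 or 2, HAMSAB_WT_M replicates 1, 2 or 3, or zero_fiber_WT_F replicates 3 or 4, and no low-count filter gave 505. The fold changes moved less: over the 14 fits without 1 library they were 2.65 to 3.27 for Spock1, 2.44 to 2.91 for Itgax (highest adjusted p 0.0539), 1.86 to 2.09 for Pced1b and 1.57 to 1.86 for Cux2, but 1.90 to 4.17 for Kif7 and 1.06 to 1.67 for Ccl4, and no named gene changed sign. Spock1, Itgax, Ccl4 and Ccl24 were each called in 13 of the 14 fits. H2-Q7 was called in 3, Rtp4, Olfr111 and Cdk5rap1 in 4, Nlrc5 in 5, Det1 in 6, Csf1 and Syt6 in 7, and the other named genes in 10 to 12.

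HAMSAB against control in WT mice gave 25 genes higher and 9 lower. Sdc4, a heparan sulfate proteoglycan of the cell surface (chromosome 2, 164424247 to 164443887), rose from 56.2 ± 17.7 to 105 ± 34.3 CPM (SD, n = 8 each; log2 0.92 ± 0.19, SE). Nod1, a sensor of bacterial peptidoglycan (chromosome 6, 54923949 to 54972612), rose from 27.01 ± 7.60 to 47.01 ± 11.9 CPM, and Tnfsf13b, the B cell factor BAFF, from 5.18 ± 1.96 to 12.01 ± 5.93 CPM. The presynaptic genes Nrxn2 (3.13 ± 0.75) and Pclo (1.70 ± 0.34), Slbp, a binding protein of histone mRNA (0.90 ± 0.20), Snhg5, Epb41l3, St5 and Got1 (0.75 to 0.73) rose. The ribosomal protein gene Rpl7 (-0.77 ± 0.17), Gtf2f2, a general transcription factor (-0.70 ± 0.14), Mia2, Tmem44, Stk10, the ubiquitin ligase Cbl, Irf2bp1 and Bank1 (-0.63 to -0.40) fell. Rpl7 ranged from 188 to 911 CPM among the control libraries and from 159 to 209 CPM among the HAMSAB libraries.

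By list, disease-associated genes were higher on HAMSAB than on control in WT mice (27 of 31, 0 called, 3 over the list alone; median 0.17, camera adjusted p = 0.00254), as were the mitochondrial genome (7 of 7, 0 called, 3 over the list alone; median 0.37, adjusted p = 0.0041) and neuron genes (6 of 6, median 0.66, adjusted p = 0.0338). Homeostatic genes were lower (19 of 21, median -0.14, adjusted p = 0.00442). With an estimated correlation these adjusted p were 0.464, 0.464, 0.467 and 0.464. Among control WT libraries only 1 of 8 had a title number below 2900, against 5 of 8 HAMSAB WT libraries. With a term for the title series edgeR called 1 gene in place of 34, and the homeostatic and neuron calls ended (adjusted p = 0.258 and 0.287). The neuron call held in 11 of 16 fits without 1 library (highest 0.106, without HAMSAB_WT_M replicate 2). Only the libraries compared gave 4 genes, DESeq2 74, voom with weights 102 and no low-count filter 433. The count was 1 or 2 without HAMSAB_WT_F replicate 1, HAMSAB_WT_M replicates 1 or 3, control_WT_F replicate 2 or control_WT_M replicate 3. It was 7 without HAMSAB_WT_M replicate 2, 11 without control_WT_F replicate 3, 65 without control_WT_M replicate 1, 76 without HAMSAB_WT_F replicate 3 and 164 without HAMSAB_WT_M replicate 4. Of the 16 fits without 1 library Nrxn2 was called in 2, Sdc4 and Nod1 in 10, Gtf2f2 in 12, and the other named genes in 3 to 11.

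Zero fiber against control in WT mice gave 1 called gene, Gm38319, a predicted gene (chromosome 1, 13641483 to 13642748), at 9.22 ± 1.46 CPM on control and 27.2 ± 15.5 CPM on zero fiber (log2 1.62 ± 0.22, SE; adjusted p = 2.8e-05). Catalase (Cat, -0.69 ± 0.14), the neuronal RNA Bc1 (1.32 ± 0.28), Atad3a, a mitochondrial ATPase (-0.90 ± 0.19), and Ccl24 (1.11 ± 0.24) came next and were not called. All 28 interferon genes were lower on zero fiber (0 called, 6 over the list alone; median -0.52, camera adjusted p = 5.2e-09, 0.388 with an estimated correlation), by -0.39 in the lower title series, which held 1 control library, and -0.59 in the higher. Erythroid and choroid plexus genes were higher (4 of 5, 0 called, 4 over the list alone; median 2.12, camera adjusted p = 5.4e-07, 0.0362 with an estimated correlation), with hemoglobin transcripts at 286 ± 298 against 53.2 ± 27.6 CPM (exact permutation p = 0.00466, adjusted over 54 tests 0.0923).

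Camera also called astrocyte (5 of 5 higher, median 0.57), perivascular (9 of 9, 0.61) and respiratory chain genes (15 of 20, 0.08) higher, and disease-associated (23 of 31 lower, -0.13), MHC class I (8 of 10, -0.15) and sterol synthesis genes (12 of 14, -0.19) lower on zero fiber than on control in WT mice. With an estimated correlation the adjusted p were 0.267, 0.388, 0.637, 0.405, 0.388 and 0.388. With the title series as a term the perivascular, disease-associated, MHC class I and sterol calls ended (adjusted p = 0.148, 0.2, 0.326 and 0.0831). The respiratory chain call ended with the length trend removed (0.241, at a median of 0.04). Without single libraries the disease-associated, MHC class I, sterol, respiratory chain and astrocyte calls held in 8, 10, 6, 10 and 13 of 14 fits. The highest adjusted p came without zero_fiber_WT_M replicate 2 (0.83, 0.164 and 0.326) for the first 3 and without zero_fiber_WT_M replicate 1 (0.396 and 0.116) for the others. The gene count was 7 in DESeq2, 8 with the series term, 12 with only the libraries compared, 2 without the doubted libraries and 183 with no low-count filter. It was 2 without zero_fiber_WT_F replicates 1 or 4, control_WT_F replicate 2 or control_WT_M replicate 2, 3 without zero_fiber_WT_M replicate 2, 6 without control_WT_F replicate 3 and 8 without control_WT_M replicate 4.

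AD was compared with WT within each diet. On HAMSAB, 178 genes were lower and 26 higher in AD. Myh9, the heavy chain of nonmuscle myosin (chromosome 15, 77760587 to 77842175), stood at 1548 ± 395 CPM in WT and 614 ± 237 CPM in AD mice (SD, n = 8 each; log2 -1.34 ± 0.25, SE; adjusted p = 0.0035). Khsrp, a splicing regulator (chromosome 17, 57021051 to 57031522), stood at 190 ± 44.5 and 72.2 ± 33.2 CPM. Rxfp1, the relaxin receptor (-2.31 ± 0.57), Spock1 (-1.75 ± 0.38), the kinase Stk35 (-1.53 ± 0.31), Ccdc85c (-1.50 ± 0.31), Pced1b, Rbm45 and Pik3c2b, a phosphoinositide kinase (-1.35 to -1.33), and Hdac4, a histone deacetylase (-0.51 ± 0.13), were lower as well. The ribosomal RNA gene n-R5s25 was lower too (-1.58 ± 0.37).

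Genes higher in AD on HAMSAB included Gnb4, a G protein beta subunit, at 1.70 ± 1.36 CPM in WT and 23.6 ± 15.1 CPM in AD (log2 3.69 ± 0.78, SE), and Trim12a, a tripartite motif gene, at 2.77 ± 1.60 and 25.8 ± 16.8 CPM. Cenpe, a kinetochore motor (1.12 ± 0.30), Rpl11 (0.70 ± 0.11), Rpl23 (0.41 ± 0.10), Igsf8, Rasl2-9, Ints13, Psma2, a proteasome subunit, Ssbp2 and Mycbp (0.83 to 0.49) were also higher. Ribosomal protein genes rose as a list (20 of 21, 1 called, 2 over the list alone; median 0.16, camera adjusted p = 1.1e-04). So did proliferation (13 of 16, 1 called and 1 over the list alone; 0.30, adjusted p = 0.0024), lysosome (16 of 19, 0 called; 0.12, adjusted p = 0.00402) and homeostatic genes (16 of 21, 0 called; 0.07, adjusted p = 0.0348). Perivascular genes fell (9 of 9, 0 called; -0.65, adjusted p = 0.0348). With an estimated correlation these were 0.548, 0.149, 0.39, 0.548 and 0.548. The homeostatic and perivascular calls held in 11 and 12 of 16 fits without 1 library (highest 0.16 and 0.11, without HAMSAB_WT_M replicate 2 and HAMSAB_AD_F replicate 3). Disease-associated genes were not called between AD and WT on HAMSAB (15 of 31 higher, median -0.0025 and mean 0.02, camera adjusted p = 0.595), with Apoe at 0.36 ± 0.20, Trem2 at 0.25 ± 0.13, Itgax at -0.04 ± 0.27 and Cst7 at -0.0025 ± 0.21.

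The Myh9 difference on HAMSAB was -1.54 in the lower title series (5 and 5 libraries) and -1.13 in the higher (2 and 3). The count of 204 was 95 without HAMSAB_WT_F replicate 1 or HAMSAB_AD_M replicate 2, 102 without HAMSAB_AD_M replicate 4, 116 without HAMSAB_WT_M replicate 1, 119 without HAMSAB_AD_F replicate 4, 128 without HAMSAB_WT_M replicate 3 and 134 without HAMSAB_WT_F replicate 2. Voom with weights called 382 genes and no low-count filter 464. In the 16 fits without 1 library Myh9, Khsrp, Stk35, Ccdc85c, Pced1b, Pik3c2b, Gnb4, Rpl11 and Ints13 were always called. Trim12a and Spock1 were called in 15, Rbm45 and n-R5s25 in 14, Rxfp1 in 11, Ssbp2 in 10, Psma2 in 9, Rpl23 in 8, Hdac4, Cenpe and Mycbp in 6, and Igsf8 and Rasl2-9 in 5.

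**Figure D2:**
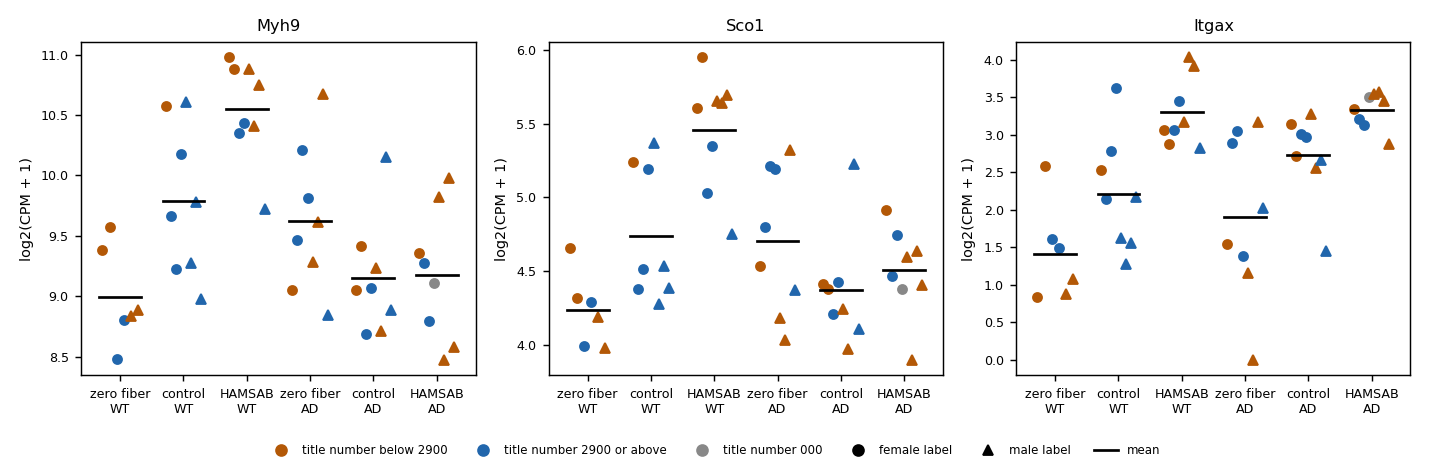
Expression of Myh9, Sco1 and Itgax as log2(CPM + 1) in each library by diet and genotype. Each point is 1 library, its color gives the series of its title number, its shape the sex label, and the line is the group mean; Myh9 and Sco1 were highest in HAMSAB WT mice, and Itgax was higher on HAMSAB than on zero fiber in both genotypes on average.

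Many genes lower in AD on HAMSAB were those higher on HAMSAB than zero fiber in WT mice: 128 genes were shared between the 178 and the 226. Both comparisons use the HAMSAB WT libraries, which alone makes their chance values run opposite. Independent lists would share 3.32 genes, while unchanged groups simulated with the same shared libraries had 0 called genes in either comparison, so that their overlap of 0 gives no chance value. Across genes, which are not independent replicates, the fold changes correlated at r = -0.535, against -0.44 to -0.428 in 3 simulations, with a covariance of -0.0583 against -0.0261 to -0.0247. With the HAMSAB WT libraries split so that none was used in both comparisons, 1 gene was shared (257 and 2 called) with replicates 1 and 2 of each sex in the genotype comparison, and 0 (0 and 275 called) with them in the diet comparison, with r of -0.119 and -0.0707. The comparison that held replicates 1 and 2, all with title numbers below 2900, thus had nearly all the calls both times. Of replicates 3 and 4, 1 library lies below 2900 and 3 above.

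On the control diet edgeR called 0 genes between AD and WT, with 656 at an unadjusted p under 0.05. DESeq2 and voom also called 0, and edgeR without a low-count filter 149. Smallest in p were the postsynaptic scaffold Dlg4 (-0.51 ± 0.13, SE), the gamma-secretase subunit Psenen (-0.67 ± 0.17), the chemokine Pf4 (1.14 ± 0.30), n-R5s25 (-1.63 ± 0.44) and the sterol enzyme Lss (0.81 ± 0.22). Apoe (0.28 ± 0.20), Trem2 (0.02 ± 0.13), Cst7 (-0.19 ± 0.21), Itgax (0.60 ± 0.32) and Clec7a (0.41 ± 0.29) were not called, and the disease-associated list was not called (21 of 31 higher, median 0.05, camera adjusted p = 0.245). Perivascular macrophage genes rose in AD as a list (9 of 9 higher, 0 called over all genes, 7 over the list alone; median 1.55, camera adjusted p = 6.8e-11, 0.02 with an estimated correlation). Cd163 stood at 1.52 ± 0.901 CPM in WT and 4.88 ± 4.39 CPM in AD (log2 1.73 ± 0.50), and Mrc1 (chromosome 2, 14229392 to 14332057) at 23.2 ± 11.3 and 35.4 ± 25.5 CPM.

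The perivascular difference between AD and WT on control was 0.81 in all libraries, 1.15 in the lower title series, where WT had 1 library, and 0.25 in the higher (4 and 7 libraries). With the title series as a term camera's adjusted p with an estimated correlation was 0.11. In control AD mice Mrc1 was 42.2, 71.8, 64.0 and 53.0 CPM in the 4 libraries of the lower series and 9.29 to 15.7 CPM in the others. For Mrc1 alone the log2 difference between AD and WT was 0.46 in the lower series and -0.53 in the higher, so its rise did not hold there. Interferon genes were lower in AD (27 of 28, 0 called, 0 over the list alone; median -0.38, camera adjusted p = 8.6e-06, 0.549 with an estimated correlation), a call that ended without control_WT_M replicate 3 (0.11). Immediate early genes were higher (16 of 22, median 0.11, adjusted p = 0.0109) and erythroid genes lower (4 of 5, median -1.32, adjusted p = 0.00732), both 0.373 with an estimated correlation. The immediate early call held in 13 of 16 fits without 1 library (highest 0.143, without control_AD_M replicate 3).

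**Figure D3:**
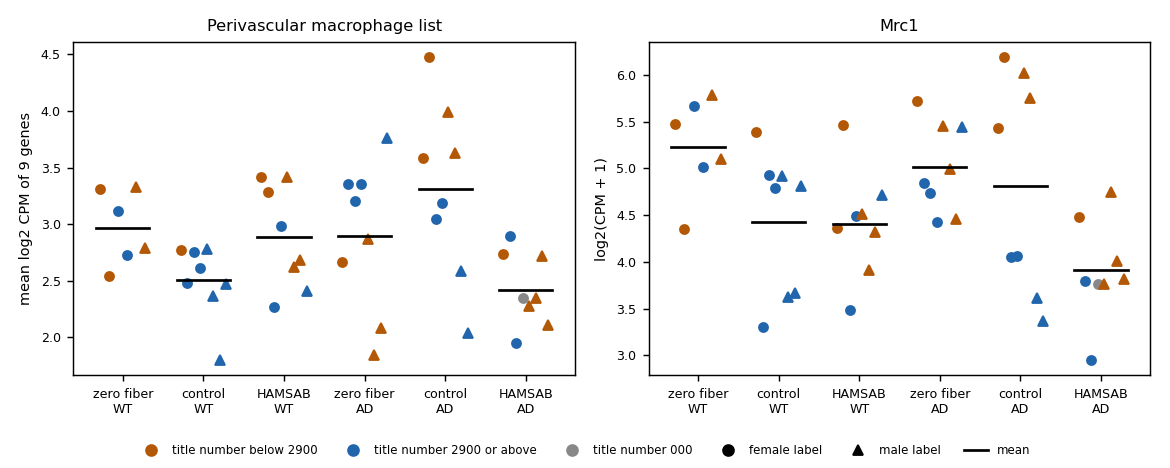
Mean log2 CPM of 9 perivascular macrophage genes (left) and Mrc1 as log2(CPM + 1) (right) in each library by diet and genotype. Each point is 1 library, its color gives the series of its title number, its shape the sex label, and the line is the group mean; in control AD mice the 4 libraries with title numbers below 2900 lay above the 4 others in both panels.

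On the zero-fiber diet 1 gene was called between AD and WT, Gm38319, lower in AD (10.2 ± 5.46 against 27.2 ± 15.5 CPM; log2 -1.23 ± 0.22, SE; adjusted p = 0.02), with 570 genes at an unadjusted p under 0.05. The next smallest p belonged to Ddx3y (3.36 ± 0.69), Gm48611 (-1.03 ± 0.22), Eif2s3y (3.14 ± 0.67) and Kdm5d (3.79 ± 0.81), not called, 3 of them Y-linked, with log2 fold changes of 2.0, 1.78 and 2.75 for Ddx3y, Eif2s3y and Kdm5d without the 2 doubted libraries, among them the library labelled zero_fiber_AD_F replicate 1. Respiratory chain genes (17 of 20 lower, median -0.12) and erythroid genes (4 of 5 lower, -0.53) were called lower by camera, both at adjusted p = 0.0127, and at 0.962 and 0.909 with an estimated correlation. They held in 9 and 10 of 14 fits without 1 library (highest 0.576 and 0.0996, both without zero_fiber_WT_M replicate 1). Neither the disease-associated (18 of 31 higher, median 0.04, adjusted p = 0.545) nor the interferon list (13 of 28 higher, -0.06, adjusted p = 0.665) was called. The count was 0 without zero_fiber_WT_M replicate 1, zero_fiber_WT_F replicate 3 or zero_fiber_AD_M replicates 1 or 4. It was 2 without zero_fiber_AD_F replicate 1, zero_fiber_AD_M replicate 3 or zero_fiber_WT_F replicate 4, 3 without zero_fiber_AD_F replicate 2 and 5 without zero_fiber_AD_F replicates 3 or 4. It was 3 in DESeq2, 6 with the series term, 2 without the doubted libraries, 0 with only the libraries compared and 93 with no low-count filter.

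No gene was called between AD and WT in the same direction on 2 diets (0 shared, where 1 and 178 independent calls would share 0.0147). With 0 genes called on control and 1 on zero fiber almost nothing could be shared, so this overlap does not show that the diets differed. It was 97 genes with no low-count filter, where 149, 93 and 464 genes were called on control, zero fiber and HAMSAB, and 0 in DESeq2, in voom and with the series term. Whether the genotype difference changed with the diet was tested directly, and 37 genes were called by edgeR's F test, which has no direction. They included Cat, the hydrogen peroxide enzyme (adjusted p = 0.0048), Camk2d, a calmodulin kinase subunit (0.0058), Sco1, a copper chaperone of cytochrome oxidase, and Dyrk1a, a kinase (both 0.0075), Myh9, Iqsec1, Med13l, Fnip2, Snd1, Hyou1, Dnajb12, Pced1b, Khsrp, Fbxw7, Btbd3, Stoml1, Rab12, Rpl11, Hnrnpl and Plau. Catalase stood at 55.5 ± 12.95 CPM on zero fiber, 81.4 ± 11.4 on control and 98.4 ± 13.2 on HAMSAB in WT mice, and at 71.0 ± 29.2, 71.0 ± 6.57 and 63.9 ± 10.5 in AD mice. Camk2d stood at 180 ± 27.5, 266 ± 66.7 and 335 ± 46.4 CPM in WT, and 262 ± 63.3, 200 ± 39.2 and 201 ± 52.7 in AD.

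The count of genes whose genotype difference changed with the diet was 0 without either zero-fiber WT male, and 2 to 9 without zero_fiber_AD_M replicate 3, HAMSAB_WT_F replicate 1, HAMSAB_WT_M replicate 3 or zero_fiber_AD_F replicate 3. It was 12 to 21 without HAMSAB_AD_M replicates 2 or 4, HAMSAB_AD_F replicates 3 or 4, HAMSAB_WT_F replicate 2, HAMSAB_WT_M replicate 1, zero_fiber_WT_F replicates 3 or 4, or zero_fiber_AD_F replicate 4. It was 58 to 78 without zero_fiber_AD_F replicate 1, zero_fiber_AD_M replicate 1, zero_fiber_WT_F replicate 2, HAMSAB_AD_M replicates 1 or 3, HAMSAB_WT_M replicate 4, control_AD_M replicate 3 or control_WT_M replicate 1, and 99 without zero_fiber_AD_M replicate 4. All 37 were called with the series term (88 genes) and without the doubted libraries (70); DESeq2 called 82, voom 58 and no low-count filter 397.

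Averaged over the diets, AD differed from WT in 3 genes in males. Actn1, an actin cross-linker (chromosome 12, 80167547 to 80260371), was higher in AD males (log2 1.20 ± 0.23, SE), and Gm38319 (-0.97 ± 0.19) and Sec22a, a vesicle trafficking gene (-0.55 ± 0.11), were lower. Gm38142 (-1.43 ± 0.30) and Maml3 (-0.46 ± 0.10) were not called. Actn1 stood at 48.4 ± 13.8 CPM in zero-fiber AD males and 10.8 ± 0.967 CPM in zero-fiber WT males (n = 4 and 2). In AD males erythroid genes were lower (4 of 5, 0 called, 4 over the list alone; median -1.99, camera adjusted p = 3.3e-06, 0.0279 with an estimated correlation). Ribosomal (14 of 21 higher, median 0.09), lysosome (17 of 19, 0.05), proliferation (14 of 16, 0.17) and homeostatic genes (18 of 21, 0.04) were called higher, at 0.709, 0.561, 0.532 and 0.709 with an estimated correlation, and all 4 calls ended with the length trend removed (0.0559 for each). Their adjusted p before were 0.0194, 0.0303, 0.0446 and 0.0446, and their medians with the trend removed were 0.08, 0.05, 0.16 and 0.04, so the calls ended near the threshold with little change of the medians. The count of 3 was 0 without zero_fiber_WT_M replicate 1, zero_fiber_AD_M replicates 1 or 3, HAMSAB_WT_M replicates 2 or 3, HAMSAB_AD_M replicates 2 or 4, control_WT_M replicate 1 or control_AD_M replicate 4. It was 1 without control_AD_M replicates 1, 2 or 3, zero_fiber_AD_M replicate 4 or control_WT_M replicate 3, and 5 without HAMSAB_AD_M replicate 1. Actn1 was called in 10, Gm38319 in 9 and Sec22a in 4 of these 22 fits. Voom, the series term and a fit of males alone called 0, DESeq2 4 and no low-count filter 66.

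In females edgeR called 0 genes between AD and WT (573 at an unadjusted p under 0.05; DESeq2 0, voom 0, edgeR with no low-count filter 114). Rxfp1 (-1.87 ± 0.42, SE), the autophagy gene Atg7 (-0.38 ± 0.10), Vcpkmt (1.26 ± 0.33) and the GTPase Hras (-0.45 ± 0.12) had the smallest p with the pseudogene Rpl34-ps2. Ribosomal (16 of 21 higher, median 0.09, camera adjusted p = 2.3e-04) and proliferation genes (13 of 16, 0.20, 0.002) were called higher and interferon genes lower (24 of 28, -0.17, 0.012), at 0.622, 0.14 and 0.805 with an estimated correlation; the interferon call ended with the series term (0.385). The difference between the sexes in the genotype effect was called in 0 genes by edgeR (413 at an unadjusted p under 0.05; DESeq2 1, voom 0, no low-count filter 27), with Actn1 (-1.56 ± 0.31) and Sec22a (0.65 ± 0.15) smallest in p. By list, erythroid genes differed (4 of 5 positive, 0 called, 3 over the list alone; median 1.94, camera adjusted p = 3.0e-04, 0.227 with an estimated correlation). It was 1 without control_AD_M replicate 3, HAMSAB_WT_M replicate 4 or control_WT_M replicate 4 and 2 without zero_fiber_WT_F replicate 4.

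Females were compared with males within each genotype. Xist (log2 8.82 ± 0.59 in WT and 8.73 ± 0.50 in AD, SE) and the Y-linked Ddx3y (-7.78 ± 0.54 and -6.42 ± 0.51), Eif2s3y, Kdm5d and Uty led both lists. The library labelled zero_fiber_AD_F replicate 1, of male pattern, was counted among the AD females, so the AD values of these genes include its reads. Over the 24 fits without 1 library Ddx3y in AD ran from -7.32 to -6.25. Kdm6a, an X-linked histone demethylase known to escape X inactivation (chromosome X, 18162575 to 18279936), was higher in females (0.63 ± 0.11 in WT and 0.54 ± 0.10 in AD), at 83.6 ± 11.2 against 45.97 ± 4.64 CPM in control WT mice (n = 4 each). In WT mice Spen, a repressor in X inactivation (-0.59 ± 0.12), Sec22a (-0.51 ± 0.11) and the splicing factor Prpf4 (-0.49 ± 0.11) were lower in females, giving 2 genes higher and 7 lower. In AD mice Actn1 was lower in females (-1.17 ± 0.21), giving 2 higher and 5 lower.

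The interferon response list was lower in females than in males in both genotypes, in AD with 27 of 28 lower, 0 called and 5 over the list alone (median -0.33, camera adjusted p = 2.9e-14, 0.525 with an estimated correlation), and in WT with 27 of 28 lower and 0 over the list alone (-0.23, 4.7e-06, 0.81 with an estimated correlation). Ribosomal protein genes were lower in females in WT (17 of 21, median -0.11) and AD (19 of 21, -0.08), at 0.81 and 0.769 with an estimated correlation. Respiratory chain genes were higher (17 of 20, 0.07) and erythroid genes lower (4 of 5, -1.11) in WT females, at 0.81 and 0.593, and mitochondrial genome genes were lower in AD females (6 of 7, median -0.27; 0.525 with an estimated correlation), a call that ended with the series term (0.119). The WT count of 9 was 15 without HAMSAB_WT_F replicate 1 and 6 without zero_fiber_WT_M replicate 1, zero_fiber_WT_F replicate 3, control_WT_F replicate 1, control_WT_M replicate 1 or HAMSAB_WT_F replicates 3 or 4. Spen, Sec22a and Prpf4 were called in 13, 12 and 9 of the 22 fits without 1 library. DESeq2 called 14, and no low-count filter gave 89 in WT and 82 in AD.

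The diets were also compared within each sex of the AD mice (n = 4 each). In males HAMSAB raised H2-K1 over zero fiber (log2 1.29 ± 0.22, SE; adjusted p = 0.0043), with the MHC class I list higher (9 of 10, 1 called, 4 over the list alone; median 0.42, camera adjusted p = 5.8e-10, 0.00322 with an estimated correlation). All 28 interferon genes were higher (0 called, 5 over the list alone, median 0.85, camera adjusted p = 2.0e-14, 0.176 with an estimated correlation). In these males camera called 5 of the 22 lists higher and 3 lower, and 2 were called with an estimated correlation. Tshz1 fell (-1.22 ± 0.24). In females H2-D1 (1.11 ± 0.23), H2-M3 (1.05 ± 0.22), H2-K1 (0.99 ± 0.20) and Cd1d1, a lipid-presenting class I-like gene (0.81 ± 0.17), rose, and Epb41l4a (-2.23 ± 0.48), Maml3 (-0.77 ± 0.16) and the 4 Y-linked genes fell. The MHC class I list (10 of 10 higher, 2 called, 3 over the list alone; 0.31, 8.0e-06, 0.0453 with an estimated correlation) and the interferon list (28 of 28, 0 called, 4 over the list alone; 0.56, 3.0e-09, 0.228) were higher in females too. The female count of 10 was 1 without the library labelled zero_fiber_AD_F replicate 1, and 1 without both doubted libraries, with none of the 10 shared. It was 4 to 6 without HAMSAB_AD_F replicates 1, 2 or 3 or zero_fiber_AD_F replicates 2, 3 or 4. In the 8 female fits without 1 library the Y-linked genes were called in 7, H2-D1 in 3, H2-K1 in 2, H2-M3 in 1, and Cd1d1, Epb41l4a and Maml3 in 0. The male count of 2 was 5 without zero_fiber_AD_M replicate 1, 19 without zero_fiber_AD_M replicate 3 and 1 without HAMSAB_AD_M replicates 2 or 3, with H2-K1 called in 7 and Tshz1 in 4 of the 8 male fits.

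HAMSAB against control gave 4 higher genes in AD males, H2-T23 (log2 0.99 ± 0.20, SE), Cstf3, a cleavage stimulation factor (0.90 ± 0.17), Rpl11 (0.80 ± 0.16) and Immt, a mitochondrial cristae protein (0.71 ± 0.14), all at adjusted p = 0.0346. In AD females Ramp1 (1.0 ± 0.18) and Cd83, an activation marker (0.91 ± 0.18), rose and Cep85l (-0.99 ± 0.20) and Trio (-0.79 ± 0.16), fell. Interferon genes were higher in both sexes (males 28 of 28, median 0.50; females 24 of 28, 0.60; 0.339 and 0.739 with an estimated correlation), and perivascular genes lower (9 of 9 in both; -1.51 and -1.47; 0.339 and 0.394). The male count was 0 or 1 without HAMSAB_AD_M replicates 1 or 3 or any control AD male, and 10 without HAMSAB_AD_M replicate 2. Each male gene was called in 1 or 2 of 8 fits and each female gene in 2 or 3. The female count was 0 to 2 without control_AD_F replicates 1, 2 or 4 or HAMSAB_AD_F replicates 1, 3 or 4, 28 without HAMSAB_AD_F replicate 2 and 168 without control_AD_F replicate 3, and DESeq2 called 9 and 53.

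Zero fiber against control in AD males gave Sap130, a subunit of a histone deacetylase complex (log2 2.25 ± 0.41, SE), and Rasgrf2, a Ras exchange factor (1.90 ± 0.39), higher and Gaa, the lysosomal alpha-glucosidase (-0.74 ± 0.15), lower. Sap130 stood at 158 ± 145 CPM in zero-fiber and 21.7 ± 3.07 CPM in control AD males. Neuron genes were higher (6 of 6, 0 called, 3 over the list alone, median 1.37, camera adjusted p = 1.4e-05, 0.0416 with an estimated correlation). Camera called 3 of the 22 lists higher and 5 lower in these males, and 1 was called with an estimated correlation. In AD females the 4 called genes were Ddx3y, Eif2s3y, Kdm5d and Uty (7.13 to 4.59), and without the 2 doubted libraries 5 genes were called, 1 of them shared (Ddx3y, log2 4.43, adjusted p = 0.0339). The male count was 0 without zero_fiber_AD_M replicate 1 or any 1 of the 4 control AD males, 5 without zero_fiber_AD_M replicate 4 and 22 without zero_fiber_AD_M replicate 3, and DESeq2 called 16. Whether the diet differences of AD mice depended on sex was called for 5 genes, Ddx3y, Eif2s3y, Kdm5d, Uty and Sap130 (adjusted p = 9.1e-04 to 0.048). The count was 0 without zero_fiber_AD_F replicate 1, and 9 and 15 without zero_fiber_AD_M replicates 4 and 3. It was 0 in voom with weights and 145 with no low-count filter.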

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

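The tests of other splits of the libraries, of the chromosome segments, of the title series, of other cell types, of the length trend and of the 2 doubted libraries were chosen after the data were seen. In 209 tests, each of 1 measure in 1 group of 4 libraries, 11 found a library that stood apart by Dixon's test. Chance gives about 1 in 20 tests, or 10.45.

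Xist was 0.00642 log2 CPM in the library labelled zero_fiber_AD_F replicate 1 and 9.71 to 9.86 in the rest of its group. Ddx3y was 6.95 in zero_fiber_AD_M replicate 2 and 7.06 in the others (7.057 to 7.063). Cst7, a cystatin of disease-associated microglia, was 4.97 in HAMSAB_WT_F replicate 3 against 3.93 to 4.07. P2ry12 was 11.98 in control_AD_M replicate 1 against 12.70 to 12.81, and 12.01 in zero_fiber_WT_F replicate 1 against 12.47 to 12.51. The interferon list mean was 4.01 in HAMSAB_AD_F replicate 4 against 4.77 to 4.88, 5.54 in HAMSAB_AD_M replicate 2 against 4.83 to 4.92, and 4.45 in zero_fiber_WT_F replicate 2 against 3.99 to 4.03, a library whose MHC class I mean also stood apart (7.29 against 6.99 to 7.04). The lysosome mean was 7.71 in HAMSAB_WT_F replicate 4 against 7.46 to 7.48, and the erythroid mean was 5.13 in HAMSAB_WT_F replicate 1 against 2.45 to 2.90. The genotype difference changed with the diet in 37 genes, and the diet difference of AD mice with sex in 5 genes, 4 of them Y-linked.

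MHC class I and interferon genes were higher on HAMSAB than on zero fiber in AD mice, with all 38 members of both lists positive. The 30 members outside the chromosome 1 and 17 segments had a median log2 fold change of 0.68, all 30 positive. This argues against segments that act only on the genes inside them as the sole cause. It cannot decide about a segment that acts on genes elsewhere, since the 30 genes may vary together. The median was 0.62 with the length trend removed and 0.74 without the 2 doubted libraries, which argues against these as the cause. The 8 members inside the segments (median 0.29) stay open to the segments, although H2-D1 ran opposite to H2-Ob within groups, and a diet effect may account for the rest, as a hypothesis.

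Genes called between HAMSAB and control in AD mice lay near each other on chromosomes 1 and 17, with 6 pairs within 5 Mb among 9 genes. None (0) of 10000 random sets of 9 genes had as many (highest 4; smallest possible share 1e-04), which argues against unrelated neighbours. Within groups, 6 of the 20 genes most correlated with Ifi202b, in either direction, lay within 10 Mb of it (0.233 by chance, Fisher's exact p = 7.6e-08), and 11 of the 20 most correlated with H2-Ob (0.436 by chance, Fisher's exact p = 6.1e-14), 8 of these 11 opposite to it, the class I genes H2-D1, H2-Q4 and H2-T22 among them. Chromosome segments of another strain carried by some mice may therefore account for H2-Ob, Slamf8, Olfml2b and Ifi202b, and stay open for H2-K1 and H2-T23, which share the chromosome 17 window and 3 of the 6 pairs with H2-Ob but were not among those 20, and which rose with H2-Ob on HAMSAB where the class I genes above ran opposite to it within groups. No genotypes were analysed here, and a diet effect on these 6 genes stays open. Igsf8, called higher in AD than WT on HAMSAB, correlated most with Ifi202b, so that call stays open to the segment. Between HAMSAB and zero fiber in AD the 29 called genes held 16 pairs (random sets at most 12). Slamf8 and H2-K1 were called there, so they stay open to the segments. Between zero fiber and control in AD the 7 held 6 (at most 3). In both, 4 Y-linked genes add pairs, so neither count argues for the segments. For AD against WT on HAMSAB and HAMSAB against either diet in WT, most random sets held as many.

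Perivascular macrophage genes were higher in AD than WT mice on the control diet (median log2 fold change 1.55). Neuron, astrocyte and oligodendrocyte lists had medians of -0.31, 0.11 and -0.03 (median of the 3 values -0.03), which argues against more cells of every other type, and the median was 1.54 with the length trend removed, which argues against that trend. With the title series as a term it was 1.29, but the estimated-correlation adjusted p went from 0.02 to 0.11. In the higher series (4 and 7 libraries) the list means differed by 0.245. The lower held 1 WT library, so it cannot separate series from genotype. More perivascular macrophages in its 4 AD libraries may account for the pattern.

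In splits of the same libraries into groups of the same sizes, chance could be excluded for AD against WT on HAMSAB (204 genes; 2 of 100 splits as large, highest other 242), HAMSAB against control in AD (9; 1 of 100, highest other 2) and WT (34; 1, highest other 5), HAMSAB against zero fiber in AD (29; 1, highest other 6) and WT (265; 1, highest other 58), the change of the genotype difference with diet (37; 2, highest other 153), and sex in WT (9; 1, highest other 1) and AD (7; 1, highest other 1). The share was also under 0.05 for HAMSAB against control in AD males (4, 1 of 35, highest other 0) and females (4, 1 of 35, highest other 0). It was under 0.05 too for zero fiber against control in AD (7, 3 of 100, highest other 29). The same held for HAMSAB against zero fiber in AD females (10, 1 of 35, highest other 6). In both, 4 of the genes are Y-linked, and the counts were 0 and 1 without the library labelled zero_fiber_AD_F replicate 1. These 2 counts therefore depend on a doubted label. The split that gave 242 genes had 7 of 8 libraries from the lower title series in one arm and 3 of 8 in the other, and with the title series as a term the real split gave 153 genes.

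For AD against WT on control (0 genes; 100 of 100 splits, highest other 7) and in females (0; 100, highest other 7) and for sex by genotype (0; 100, highest other 5), every split gives at least the real count of 0, so the splits say nothing. At least 0.05 of the splits gave as many genes for AD against WT on zero fiber (1, 35 of 100, highest other 20) and in males (3, 8, highest other 229). So they did for zero fiber against control in WT (1, 14, highest other 169) and sex by diet in AD (5, 13, highest other 9). The same held for zero fiber against control in AD males (3, 2 of 35, highest other 94) and females (4, 15, highest other 6). It also held for HAMSAB against zero fiber in AD males (2, 2, highest other 3). Splits with 20, 29, 94, 153, 169 and 229 genes, several times the real counts, point to a structure of the samples, which was not identified. The lower title series held 6 of 8 and 2 of 6 libraries of the arms in the split with 20 genes, but 3 of 8 and 5 of 8 in that with 29, 2 of 4 and 3 of 4 in that with 94, 2 of 6 and 3 of 8 in that with 169 and 8 of 12 and 6 of 10 in that with 229, so the title series alone does not describe them.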

How the results depend on the processing

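The fits without the 2 doubted libraries and with the length trend removed, and the alternatives for the overlap of genotype calls, were chosen after the data were seen. No called gene that is named reversed its direction in the alternative fits below, nor did a called list with an estimated correlation, with fry, with the series as a term, with the length trend removed or without the doubted libraries, the fits in which lists were tested for direction. Lists that were not called did change sign: between HAMSAB and zero fiber in AD mice the homeostatic median of 0.0016 was -0.0108 with the length trend removed and -0.074 without the doubted libraries, where the MHC class II median of 0.19 was -0.03. With the title series as a term the interferon median between AD and WT on zero fiber went from -0.06 to 0.02, and the disease-associated median on HAMSAB from -0.0025 to 0.03. Within 1 title series called lists could turn too, as the perivascular difference between zero fiber and control in AD mice did (-1.55 and 0.71). In the alternative fits the largest shift of the median of all genes was 0.0165. Of the named genes, the call stayed on its side of the threshold in 144 with DESeq2 size factors (2 lost), 156 with DESeq2 (10 lost, 15 gained), 120 with voom (26 lost), 135 with the title series as a term (38 lost, 8 gained), 96 with only the libraries compared (43 lost, 2 gained), 125 with no low-count filter (4 lost, 17 gained), 146 without the doubted libraries (30 lost, 5 gained) and 155 with the length trend removed (23 lost, 3 gained). The cause was not tested for any count below unless stated. No paired analysis was possible, since replicate numbers pair no samples.

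With no low-count filter 31448 genes were tested, and the counts were 149, 93 and 464 for AD against WT on control, zero fiber and HAMSAB, 357, 269 and 204 in AD and 433, 183 and 505 in WT for HAMSAB against control, zero fiber against control and HAMSAB against zero fiber. They were 397 for diet by genotype, 66 in males, 114 in females, 27 for sex by genotype, 89 and 82 for sex in WT and AD, 145 for sex by diet in AD and 97 for the overlap of genotype calls across diets. Most of these calls lay among the 12121 genes that pass the filter (147 of 149 for AD against WT on control).

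DESeq2 called 3 genes for AD against WT on zero fiber, 80, 16 and 52 for the diet comparisons in AD, 74 and 7 for HAMSAB and zero fiber against control in WT, 82 for diet by genotype, 1 for sex by genotype, 14 for sex in WT, 9, 16 and 10 in AD males, 53 for HAMSAB against control in AD females and 8 for sex by diet in AD. Voom with quality weights called 382 for AD against WT on HAMSAB, 72 and 0 for HAMSAB and zero fiber against control in AD, 102 for HAMSAB against control in WT, 58 for diet by genotype, 0 in males and 0 for sex by diet in AD.

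With the title series as a term the counts were 6 for AD against WT on zero fiber, 25 for HAMSAB against control in AD and 1 in WT, 8 for zero fiber against control in WT, 88 for diet by genotype, 0 in males, 1 and 5 for zero fiber against control and HAMSAB against zero fiber in AD males, and 2 for HAMSAB against control in AD females. With only the libraries compared they were 0 for AD against WT on zero fiber, 71 and 1 for HAMSAB and zero fiber against control in AD, 4 and 12 in WT, 0 in males and 0 for sex by diet in AD. Without the doubted libraries they were 2 for AD against WT on zero fiber, 19 and 3 for HAMSAB and zero fiber against control in AD, 2 for zero fiber against control in WT, 70 for diet by genotype, 5 for zero fiber against control in AD males, 1 for HAMSAB against zero fiber in AD females and 0 for sex by diet in AD. With the length trend removed they were 6 and 5 for zero fiber against control and HAMSAB against zero fiber in AD males, and 2 and 4 for HAMSAB against control and HAMSAB against zero fiber in AD females. Of 117 list calls, 12 held with an estimated correlation and 26 with fry.

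Leaving out each library in turn gave 0 to 0 genes for AD against WT on control, 0 to 5 on zero fiber and 95 to 281 on HAMSAB, 1 to 104, 0 to 12 and 16 to 72 for HAMSAB against control, zero fiber against control and HAMSAB against zero fiber in AD, and 1 to 164, 1 to 8 and 1 to 346 in WT. It gave 0 to 99 for diet by genotype, 0 to 5 in males, 0 to 0 in females, 0 to 2 for sex by genotype, 6 to 15 for sex in WT and 7 to 9 in AD, 0 to 10, 0 to 22 and 1 to 19 for the diets in AD males, 0 to 168, 4 to 6 and 1 to 9 in AD females, and 0 to 15 for sex by diet in AD. Depth limits zero_fiber_AD_M replicate 2 most.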

Other observations

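Lists not described above were not called in the comparisons with the most called genes, and no tests in this part were chosen after the result was seen. MHC class II genes, which present antigen to CD4 T cells, had 5 of 7 members higher on HAMSAB than on zero fiber in AD mice (median log2 fold change 0.19, camera adjusted p = 0.0713). In the same comparison 7 of 13 inflammatory cytokine and NF-kB genes (median 0.07, adjusted p = 0.182), 9 of 14 sterol synthesis genes (0.11, adjusted p = 0.971), 6 of 10 cholesterol efflux and lipid storage genes (0.10, adjusted p = 0.583) and 4 of 10 histone deacetylase genes (-0.03, adjusted p = 0.994) were higher. Homeostatic microglia genes had 11 of 21 members higher (0.0016, adjusted p = 0.93).

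In WT mice 12 of 14 sterol synthesis genes (median 0.17, camera adjusted p = 0.0689) and 8 of 10 histone deacetylase genes (0.12, adjusted p = 0.318) were higher on HAMSAB than on zero fiber, and 7 of 21 homeostatic genes (-0.05, adjusted p = 0.226). Between AD and WT mice on HAMSAB 2 of 10 histone deacetylase genes were higher (-0.10, adjusted p = 0.218), with Hdac4 called lower, a call that held in 6 of the 16 fits without 1 library.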
